A study of Mus musculus with 3 samples.

How the data were processed

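The deposited matrix held raw UMI counts, the unit count per the file headers, for 31053 genes and 11 antibody tags in 48054 barcodes of 1 pooled capture. The authors' cell table gave each of 30059 kept cells its hashtag, cluster and percent of mitochondrial UMIs, a unit of percent. For 28503 cells the gene UMI total of the matrix equalled that of the table. Per the submitters' processing notes, reads were processed with Cell Ranger ARC 1.0.1 and cells were analysed in Seurat; the matrix header names Cell Ranger 7.0.0. The genome build was not given in the sources used here.

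The cells the authors kept were used. None held more than 5% mitochondrial UMIs, the fewest genes in a cell were 301 and the lowest UMI total was 1779. All had a single hashtag, so doublets between mice were left out by the authors, and doublets within a mouse were not searched for; 5 cells held at least 2 productive beta chains. Mice were told apart by their hashtags, although the labels call the samples pooled. In mice with 1 graft every cell was assigned to that graft. In mice with both grafts a cell was assigned by its transgenic beta chain, and 1428 cells with neither chain were left out.

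UMIs were summed per mouse and population, with at least 20 cells per sum, after T cell receptor segment genes were left out. The sums were tested with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test) with 4 against 3 mice, 3 against 3 mice or 4 pairs with the mouse as a block. Log2 fold changes are those of the fitted model, an SE is the size of the log2 fold change divided by the square root of F, and p values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Group means and SDs are TMM-adjusted CPM unless stated otherwise. Gene lists were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 22 measured of 23 lists, and again with a correlation estimated per list and with fry. All lists were fixed before the data were examined, as were the comparisons. Genes eligible for naming were the 6 largest changes per direction with a mean of at least 20 CPM and no overlap between groups, up to 4 with the smallest adjusted p per list, and always Ifng, Tbx21, Foxp3 and Mki67. Some genes that met this rule are not reported here. Other genes are named where a list or another comparison held them.

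Shares of cells and tag medians were compared by exact permutation of mice, or sign flips of pairs. The smallest two-sided p were 0.0571 for 4 against 3 mice, 0.1 for 3 against 3 and 0.125 for 4 pairs. For shares of cells with a UMI every cell was thinned to 1779 UMIs. Mice shared 1 capture and library, so p values describe the spread between mice and not between repeated experiments. Cluster shares were not read as cell states where the leading genes of a cluster were themselves called; clusters 5 and 8 are given as a measure of RNA content.

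In a self-test, counts were simulated from each gene's mean level and the trended dispersion, with known changes put in. The 5 comparisons follow in the order of CBir1, Marilyn, pairs, single grafts and difference of effects. Of 1.5-fold changes 71.6, 68.7, 79.1, 71.6 and 47.8% were recovered, and of 2-fold changes 91.0, 92.5, 95.5, 86.6 and 76.1%. Of unchanged genes 9, 18, 11, 5 and 5 were called. The simulation held no dispersion of single genes, no effect of the mouse and no correlation between genes. These numbers therefore need not hold for the real sums.

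Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, at least 1000 genes per cell, cells with 2 beta chains left out, the transgenic beta chain required in both groups, 1599 cells in every sum, receptor segment genes kept, all 4 sets fitted together, no mouse block, and each mouse left out in turn. Chosen after the data were seen were cells without clusters 5 and 8, without cluster 4, the beta chain required together with clusters 5 and 8 left out, sums of 5238917 UMIs, and shares of clusters, of cells with a UMI and of receptor chains with the beta chain required. Clusters at a second resolution were not made. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.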

Results

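Donor CD4 T cells with 2 transgenic T cell receptors were recovered from the spleens of 10 male mice 6 days after stem cell transplantation and were profiled by droplet single-cell RNA sequencing, together with their receptor chains and antibody tags. Marilyn T cells recognise the male HY antigen, so cells from female donors are alloreactive in male recipients. CBir1 T cells recognise a flagellin of gut bacteria. All recipients received 5000000 bone marrow cells. In addition 3 mice received 500000 Marilyn T cells, 3 mice received 1000000 CBir1 T cells and 4 mice received both. The sort gates took donor CD4 T cells and left out CD8 cells and cells with the CD45.1 marker of the recipients and of the marrow. The sort was described as mixing Marilyn and CBir1 T cells at a set ratio of 4 to 1, so the shares of the populations are not compared. The kept cells did not show this ratio. In the mice with both grafts 8293 cells carried the Marilyn and 6987 the CBir1 beta chain.

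The authors' cell table held 30059 cells of 48054 barcodes, each assigned to a single mouse by its hashtag. UMIs were summed per mouse and population, which gave 14 sums. CBir1 T cells held 8735763 to 9467947 UMIs per mouse when given alone (2189 to 2274 cells) and 5238917 to 5922421 beside Marilyn T cells (1599 to 1869 cells). Marilyn T cells held 8497348 to 9775311 UMIs per mouse when given alone (2156 to 2290 cells) and 8389543 to 10860387 beside CBir1 T cells (2011 to 2186 cells). The median CBir1 T cell held 3140 ± 69.8 UMIs beside Marilyn T cells (mean and SD of 4 mice) and 3880 ± 115 alone (3 mice). All levels are given as CPM of a sum's UMIs, so they are shares of a population's RNA and not amounts per cell.

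The first comparison asked how CBir1 T cells of the 4 mice that also received Marilyn T cells differed from those of the 3 mice that did not. Most of their cells lay in another of the authors' clusters: 91.2 ± 1.3% were in cluster 0 beside Marilyn T cells and 3.93 ± 2.1% alone, against 0.768 ± 0.34% and 73.3 ± 1.8% in cluster 1 (SD, n = 4 and 3, exact permutation p = 0.0571 for each, two-sided, adjusted p = 0.124 over 26 tests). The 10 leading genes of each of these clusters were among the genes called. Mki67 (ENSMUSG00000031004), a marker of dividing cells, fell from 162 ± 41 to 18.3 ± 6.4 CPM (SD, n = 3 and 4, log2 fold change -3.13, SE 0.18). The interferon response gene Irf7 and the immediate early gene Junb were higher beside Marilyn T cells, and Idi1, an enzyme of cholesterol synthesis, was lower. The largest rises were in Trnp1 (ENSMUSG00000056596), a nuclear protein first described in the brain, from 0.605 ± 0.068 to 170 ± 44 CPM (log2 8.09, SE 0.27), and in Ston1 (ENSMUSG00000033855), an endocytic adaptor (log2 6.33, SE 0.22). Of 10573 genes tested, 2416 were higher and 2626 were lower in edgeR's quasi-likelihood test.

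All 30 measured members of the G2/M list fell, with a median log2 of -2.28 (adjusted p = 6.9e-18 in the list test, adjusted p = 0.28 with an estimated correlation). Top2a, which untangles DNA, changed by -2.67 (SE 0.10), and Cenpf, a kinetochore protein, by -3.02 (SE 0.23). Of 30 S phase genes 29 fell and 1 did not pass, with a median of -1.44, and this call held with an estimated correlation (adjusted p = 2.7e-18 preset and 0.043 estimated). Rrm2, a subunit of ribonucleotide reductase, changed by -2.52 (SE 0.11) and Mcm5, part of the replicative helicase, by -2.04 (SE 0.089). Outside the lists, the DNA repair gene Rad51b fell by 3.76 (SE 0.20). Rad51b and Mki67 were also leading genes of the RNA-poor cluster 8, which was rarer beside Marilyn T cells, and changed by -3.13 (SE 0.21) and -2.55 (SE 0.17) without clusters 5 and 8. With every cell thinned to 1779 UMIs, 1.76 ± 0.54% of CBir1 T cells beside Marilyn T cells had an Mki67 UMI, against 8.71 ± 1.2% alone. The exact permutation p of 0.0571 (two-sided) is the smallest that 4 mice against 3 allow. Unthinned, 2.81% and 12.6% of all cells of these sets had such a UMI, at median depths of 3128 and 3887 UMIs.

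Of 24 cholesterol synthesis and uptake genes 19 fell and 5 did not pass (median -0.71, adjusted p = 2.0e-07, and adjusted p = 0.16 with an estimated correlation). Idi1 and Sqle, enzymes of the pathway, changed by -2.07 (SE 0.16) and -2.02 (SE 0.20). Of 46 nuclear genes of oxidative phosphorylation 31 fell, 2 rose and 13 did not pass (adjusted p = 1.8e-05, 0.45 as the adjusted p with an estimated correlation). Cycs, the electron carrier cytochrome c, changed by -0.78 (SE 0.064) and Cox5a by -0.57 (SE 0.061). Of 13 mitochondrially encoded genes 12 fell and 1 did not pass (adjusted p = 3.1e-05, adjusted p = 0.44 with an estimated correlation), among them mt-Nd3 (-0.89, SE 0.097). The median percent of mitochondrial UMIs per cell was 0.822 ± 0.053 beside Marilyn T cells and 1.28 ± 0.043 alone. RNA-poor cells, those of the authors' clusters 5 and 8, made up 0.275 ± 0.28% and 9.95 ± 3.6% of the cells (exact permutation p = 0.0571 for each measure, two-sided).

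Of 50 interferon response genes 34 rose, 3 fell and 13 did not pass (median 0.56, adjusted p = 2.3e-07, and adjusted p = 0.43 with an estimated correlation). Irf7, a transcription factor of the response, rose from 41.1 ± 1.5 to 144 ± 16 CPM (log2 1.81, SE 0.086), Isg20 by 1.55 (SE 0.082) and the GTPase Irgm1 by 1.32 (SE 0.12). Of 30 genes of Th1 and cytotoxic effector function 19 rose, 6 fell and 5 did not pass (adjusted p = 0.0068, adjusted p = 0.44 with an estimated correlation). Ly6c2 rose by 3.17 (SE 0.11) and the granzyme Gzma by 1.25 (SE 0.11). The cytokine Ifng and its regulator Tbx21 rose by 1.92 (SE 0.27) and 0.78 (SE 0.22) from low levels of 1.75 ± 0.62 and 3.82 ± 0.83 CPM. Ly6c2 has a near-identical neighbour, Ly6c1, and the Ifit3 and Ifitm families hold similar copies, so UMIs could have been split between them.

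Of 24 genes of T cell receptor signalling 12 rose, 3 fell and 9 did not pass (adjusted p = 0.011, adjusted p = 0.44 with an estimated correlation). Of 21 dissociation stress and immediate early genes 14 rose, 1 fell and 6 did not pass (median 1.03, adjusted p = 0.00048, and adjusted p = 0.45 with an estimated correlation). Junb and Egr1, immediate early transcription factors, rose by 1.84 (SE 0.20) and 1.51 (SE 0.13), and Dusp2, a phosphatase of MAP kinases, by 1.41 (SE 0.12). The apoptosis and p53 list did not pass its test (11 of 23 higher, 4 lower, adjusted p = 0.057), but the BH3-only death genes Bbc3 (ENSMUSG00000002083) and Bcl2l11 rose by 3.34 (SE 0.12) and 1.56 (SE 0.12). The naive and central memory list did not pass either (7 of 24 higher, 8 lower, adjusted p = 0.69). Within it the interleukin-7 receptor Il7r rose from 164 ± 12 to 918 ± 37 CPM (log2 2.48, SE 0.069) and Tsc22d3 by 1.64 (SE 0.083). The transcription factor Klf9, which is in no list, rose by 3.23 (SE 0.16).

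The regulatory T cell list missed its threshold with 6 of 13 genes lower and 2 higher (adjusted p = 0.0504, adjusted p = 0.44 with an estimated correlation), and Foxp3 fell from 10.1 ± 3.1 to 2.38 ± 0.81 CPM (log2 -2.10, SE 0.27). At 1779 UMIs per cell 0.317 ± 0.088% and 1.41 ± 0.39% of CBir1 T cells with and without Marilyn T cells had a Foxp3 UMI, against 0.0724 ± 0.048% and 0.0921 ± 0.080% of Marilyn T cells, whose median depths were 4213 and 3830 UMIs. Unthinned, these 4 shares of all cells were 0.472, 2.40, 0.193 and 0.196%. The CBir1 T cells given alone include cells without a beta chain. With the chain required in both groups their thinned share was 0.899 ± 0.19%, so the difference shrank from -1.09 to -0.58 percentage points (exact permutation p = 0.0571 for each, two-sided), and the log2 fold change of Foxp3 was -1.33 (SE 0.26, adjusted p = 0.00038). The Th17 (4 of 6 higher, adjusted p = 0.13), Th2 (2 of 3 lower, 0.34), follicular helper (5 of 12 higher, 1 lower, 0.43), co-inhibitory (6 of 13 higher, 2 lower, 0.26), glycolysis (2 of 20 higher, 8 lower, 0.13) and homing (6 of 19 higher, 5 lower, 0.98) lists did not pass. With the transgenic beta chain required in both groups the Th17 list (adjusted p = 0.015, adjusted p = 0.21 with an estimated correlation) and the apoptosis and p53 list (0.034, and 0.40 with an estimated correlation) passed, and 2 of 12 regulatory T cell genes fell (adjusted p = 0.63). The homing and erythroid lists had medians of 0.10 and 0.03 and means of -0.01 and -0.00. Adjusted over the list alone, 20 Th1 genes rose and 6 fell, all 30 S phase genes fell, 13 receptor signalling genes rose and 32 oxidative phosphorylation genes fell, and the counts of the other lists that passed were the same.

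Markers of other cells moved in both directions. Of 20 B cell and plasma cell genes 5 were measured and all fell (adjusted p = 0.037, adjusted p = 0.32 with an estimated correlation), including Jchain (-3.63, SE 0.53) and Igkc (-1.41, SE 0.27). Jchain was at -4.84 without both-graft replicate 2 and -3.00 without CBir1 alone replicate 3. The list lost its call with the chain required in both groups (3 of 5 lower, adjusted p = 0.10) and without clusters 5 and 8 (adjusted p = 0.062), and Igkc lost its call with both changes made together (log2 -0.66, adjusted p = 0.19). The myeloid list did not pass (6 of 15 higher, 2 lower, adjusted p = 0.11), but the granulocyte genes S100a8 and S100a9 rose by 3.21 (SE 0.38) and 2.71 (SE 0.35), with 135 ± 85 CPM of S100a8 beside Marilyn T cells. S100a8 was at 3.82 without CBir1 alone replicate 1 and 2.71 without both-graft replicate 2. The CD8, NK and gamma delta list (1 of 4 higher, 2 lower, adjusted p = 0.58) and the erythroid list (0 of 4 changed, 0.98) did not pass, and none of 6 Y-linked genes was measured. The number of genes called stayed within 1.5 times under every alternative and with any mouse left out.

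**Figure D1:**
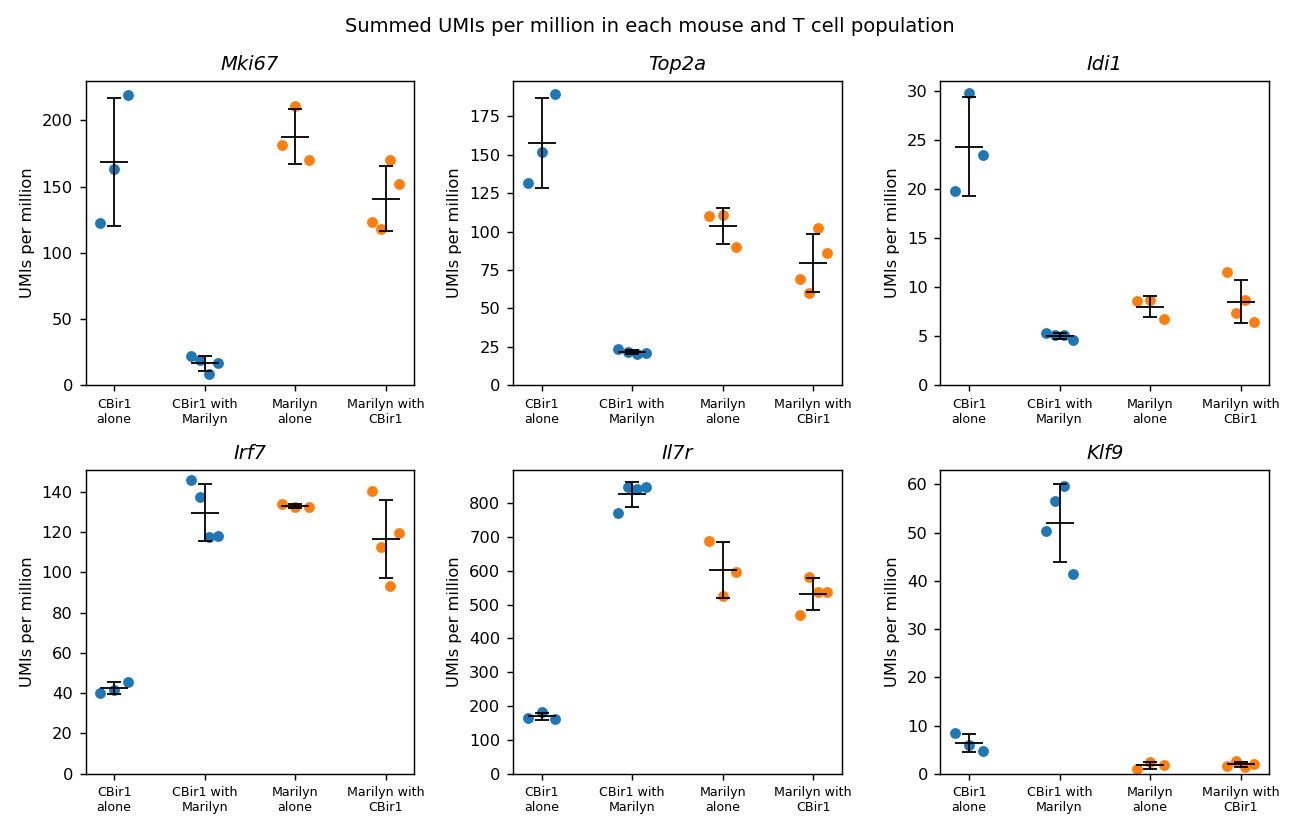
Levels of 6 genes in each mouse and population, in CPM without TMM factors (y axis, linear, from 0). Points are mice, the long bar is the mean and the whiskers are 1 SD (3 mice for each population given alone, 4 for each given together); Mki67, Top2a and Idi1 were lower, and Irf7, Il7r and Klf9 higher, in CBir1 T cells beside Marilyn T cells than in CBir1 T cells alone.

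The second comparison asked the reverse question, how Marilyn T cells of the 4 mice with both grafts differed from those of the 3 mice with Marilyn T cells alone. The immediate early genes Fos and Fosb were higher beside CBir1 T cells. Fos (ENSMUSG00000021250) rose from 44.9 ± 7.3 to 125 ± 39 CPM (SD, n = 3 and 4; log2 1.48, SE 0.19, adjusted p = 0.0077) and Fosb by 1.24 (SE 0.16, adjusted p = 0.0077). Both passed under every choice of cells tried and with any mouse left out. Jun (0.75, SE 0.12), Nr4a2 (0.91, SE 0.16) and Gadd45b (0.88, SE 0.12) rose as well, and the costimulatory receptor Tnfrsf4 fell by 0.62 (SE 0.12). These genes passed under each choice of cells, but Jun and Nr4a2 lost their calls without Marilyn alone replicate 1 or 2, and Gadd45b and Tnfrsf4 without replicate 2.

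In the deposited cells 688 genes were higher and 671 were lower of 11112 tested, but this number rests on which cells and which mice are counted. In mice with both grafts a cell needed a transgenic beta chain to be assigned to a population, while in mice with 1 graft cells without a beta chain were kept. With that chain required in both groups, 12 genes were called, 9 higher and 3 lower (1936 at an unadjusted p under 0.05). Without the RNA-poor clusters 5 and 8, 8 genes were called, 7 higher and 1 lower. The genes called with all cells had a median size of 0.32 on the log2 scale (median SE 0.080), 0.23 with the chain required (SE 0.078, 100% in the same direction) and 0.17 without these clusters (SE 0.071, 99.6%). Their median size thus fell with little change in its SE. Genes at an unadjusted p under 0.05 in edgeR's test fell from 3299 to 1936 with the chain and to 1465 without these clusters. The calls therefore did not end in the adjustment over all genes alone. Nearly all of the genes called with all cells kept their direction, which tests little, since mostly the same cells were refitted. Some genes, such as Ifng and S100a8, kept their size and lost their calls. These clusters held 7.70 ± 2.0% of Marilyn T cells beside CBir1 T cells and 19.0 ± 4.2% of those given alone, or 13.9 ± 2.8% with the chain required (exact permutation p = 0.0571, two-sided, the smallest possible). Single mice mattered too: 16, 3 and 1545 genes were called without Marilyn alone replicate 1, 2 or 3, and 253, 556, 231 and 1835 without both-graft replicate 1, 2, 3 or 4.

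In the gene lists, with all deposited cells, 36 of 46 oxidative phosphorylation genes rose and none fell (median 0.26, adjusted p = 2.1e-16, and adjusted p = 0.71 with an estimated correlation), such as Ndufb10 (0.37, SE 0.074) and Cox4i1 (0.33, SE 0.070). With the chain required 0 of the 46 passed singly, with a median of 0.18 (list adjusted p = 2.3e-13, and adjusted p = 0.60 with an estimated correlation). Of 20 stress and immediate early genes 12 rose (median 0.32, adjusted p = 2.8e-06, and adjusted p = 0.71 with an estimated correlation) and 4 of them passed with the chain required. Dusp1, a phosphatase of MAP kinases, rose by 1.14 (SE 0.19) and kept its call with the chain required but not without clusters 5 and 8 (adjusted p = 0.076). Of 33 Th1 genes 8 rose, 1 fell and 24 did not pass (adjusted p = 0.040, adjusted p = 0.71 with an estimated correlation). The chemokine genes Ccl3 and Ccl4 rose by 1.12 (SE 0.19) and 0.66 (SE 0.14) and Ifng by 0.89 (SE 0.17), from 55.2 ± 3.9 to 102 ± 28 CPM. Ifng and Ccl4 lost their calls with the chain required (0.91 and 0.64, adjusted p = 0.059 and 0.083), and Ccl3 kept its call there. Ccl3 was at 1.11 without clusters 5 and 8 (adjusted p = 0.076) and at 1.18 with both changes (adjusted p = 0.043). The early activation marker Cd69 rose by 0.62 (SE 0.11) and lost its call with the chain required (0.58, adjusted p = 0.058).

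At 1779 UMIs per cell 14.1 ± 3.1% of Marilyn T cells beside CBir1 T cells and 8.64 ± 0.46% of those given alone had an Ifng UMI, against 0.343 ± 0.14% of CBir1 T cells alone (exact permutation p = 0.0571 for the difference between Marilyn groups, two-sided). Unthinned, these 3 shares of all cells were 26.3, 16.2 and 0.611%, at median depths of 4213, 3830 and 3887 UMIs. Of 14 follicular helper genes 5 fell and 1 rose (adjusted p = 0.0022, adjusted p = 0.71 with an estimated correlation), and of 51 interferon response genes 5 fell and 1 rose (adjusted p = 0.040, adjusted p = 0.71 with an estimated correlation). The G2/M list had no member past the threshold (30 measured, adjusted p = 0.55) and Mki67 differed by -0.28 (SE 0.11, adjusted p = 0.095), though it was called without both-graft replicate 3 (-0.39, adjusted p = 0.046) and without the filter on low counts (-0.29, adjusted p = 0.0029). Tbx21 differed by -0.05 (SE 0.11, adjusted p = 0.81). The Th17 list missed its threshold (3 of 11 lower, adjusted p = 0.075) and passed with the chain required (adjusted p = 0.014, adjusted p = 0.60 with an estimated correlation), where none of its genes passed singly. The other lists did not pass. Among the largest falls were Inpp4b, a lipid phosphatase (-0.80, SE 0.12), St6galnac3 (-0.81, SE 0.22), the transcription factor gene Aff3 (-0.71, SE 0.14) and Ext1, an enzyme of heparan sulfate synthesis (-0.71, SE 0.12). St6galnac3, a leading gene of the RNA-poor cluster 5, Aff3, Ext1, Ndufb10, Cox4i1, Ccr7 (-0.61, SE 0.16), Cd200r1 (-0.90, SE 0.20) and S100a8 (-1.31, SE 0.37) were not called with the chain required, where they were at -0.59, -0.59, -0.59, 0.29, 0.24, -0.71, -0.80 and -1.29 in this order. With a mouse left out S100a8 was called only without both-graft replicate 2 (-1.95). Adjusted over the list alone, 44 oxidative phosphorylation genes, 13 stress genes and 10 Th1 genes rose, and 10 follicular helper and 5 interferon response genes fell.

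**Figure D2:**
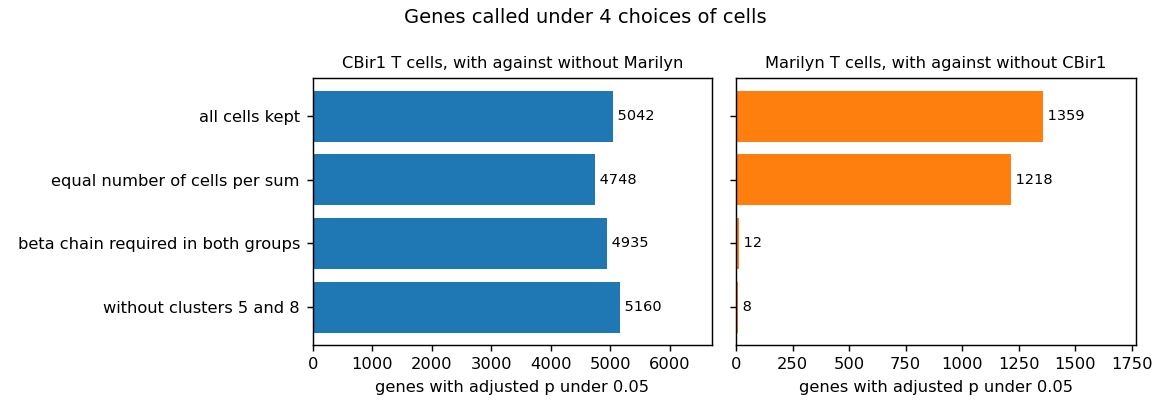
Genes with an adjusted p under 0.05 (x axes, linear, from 0, with different ends) under 4 choices of cells, for CBir1 T cells (left, blue) and Marilyn T cells (right, orange), each with against without the other graft. The bars lie between 4748 and 5160 genes for CBir1 T cells and between 8 and 1359 for Marilyn T cells.

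Whether the graft partner changed CBir1 T cells differently from Marilyn T cells was tested directly as the signed difference of both effects (CBir1 minus Marilyn). Such a difference does not tell which population changed more. The oxidative phosphorylation list, for example, had a median of -0.26 in CBir1 and 0.26 in Marilyn T cells. The 4 mice with both grafts enter this fit with both of their sums and without a term for the mouse. Of 11736 genes 1700 had a higher and 1887 a lower effect in CBir1 T cells. All 30 G2/M genes had a lower effect (median -2.40, adjusted p = 4.8e-22, and adjusted p = 0.17 with an estimated correlation), as had 29 of 30 S phase genes (median -1.54, adjusted p = 9.5e-25 preset and 0.048 estimated). For Mki67 the difference was -2.84 (SE 0.25). Of 46 oxidative phosphorylation genes 40 had a lower effect (adjusted p = 1.3e-16, adjusted p = 0.28 with an estimated correlation), as had 16 of 24 cholesterol genes (adjusted p = 2.2e-08, adjusted p = 0.13 with an estimated correlation) and 11 of 13 mitochondrially encoded genes (adjusted p = 7.4e-06, adjusted p = 0.38 with an estimated correlation). The effect was higher for 35 and lower for 1 of 51 interferon response genes (adjusted p = 2.0e-09, adjusted p = 0.28 with an estimated correlation), with Irf7 at 1.88 (SE 0.15). With the transgenic beta chain required in both groups 39 of the 46 oxidative phosphorylation genes still had a lower effect.

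Smaller shares of other lists differed in the same test. The effect in CBir1 T cells was higher for 9 and lower for 1 of 24 receptor signalling genes (adjusted p = 0.0084), higher for 5 of 16 co-inhibitory genes (0.014), for 5 of 14 follicular helper genes (0.019) and for 7 of 19 myeloid genes (0.019), and lower for 7 and higher for 1 of 21 glycolysis genes (0.048). With an estimated correlation the adjusted p of these lists were 0.40, 0.18, 0.40, 0.40 and 0.40. Fos and Fosb, which rose in both populations (1.41 and 1.09 in CBir1 T cells), had differences of -0.07 (SE 0.36, adjusted p = 0.91) and -0.15 (SE 0.27, adjusted p = 0.73). Adjusted over the list alone, 38 interferon genes and 12 receptor signalling and 8 myeloid genes had a higher effect and 42 oxidative phosphorylation and 18 cholesterol genes a lower one.

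**Figure D3:**
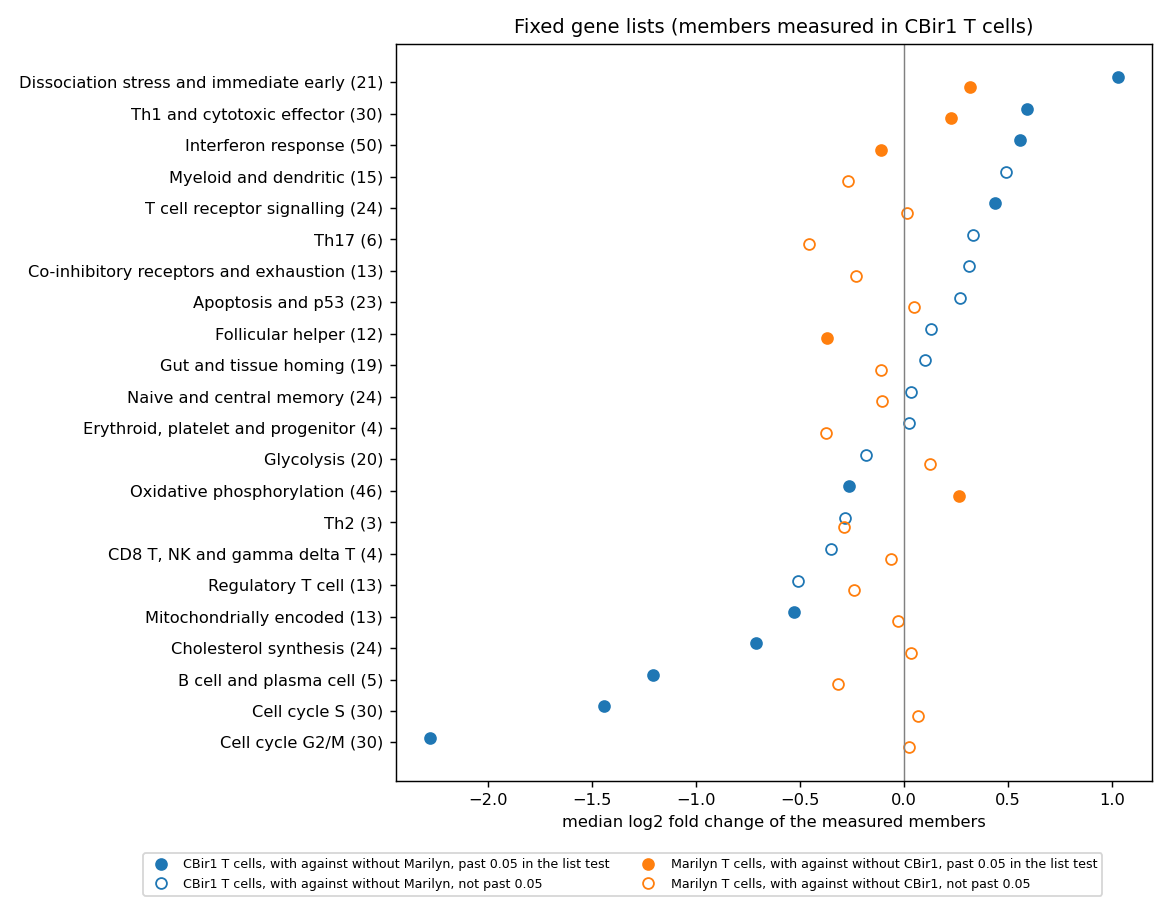
Median log2 fold change of each fixed gene list (x axis) in CBir1 T cells with against without Marilyn T cells (blue) and in Marilyn T cells with against without CBir1 T cells (orange), with the number of members measured in CBir1 T cells in parentheses. Filled points passed 0.05 in the list test with the preset correlation; the G2/M median was -2.28 in CBir1 and 0.03 in Marilyn T cells.

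Marilyn and CBir1 T cells were next compared within the 4 mice that held both, each mouse serving as its own pair. The chemokine receptor gene Cxcr6 (ENSMUSG00000048521) reached 188 ± 23 CPM in Marilyn and 4.08 ± 1.4 CPM in CBir1 T cells (SD, n = 4 pairs; log2 5.50, SE 0.12), and the granzyme Gzmk (ENSMUSG00000042385) 421 ± 27 and 12.2 ± 3.1 CPM (log2 5.10, SE 0.097). Igfbp4 (ENSMUSG00000017493), which binds insulin-like growth factors, had 12.7 ± 1.3 and 799 ± 79 CPM (log2 -5.97, SE 0.071). Of 10844 genes 3790 were higher and 3851 lower in Marilyn T cells.

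Of 33 Th1 and cytotoxic genes 31 were higher, 1 was lower and 1 did not pass (median 3.77, adjusted p = 1.4e-11, and adjusted p = 0.41 with an estimated correlation), with Ifng at 3.77 (SE 0.13), Tbx21 at 3.76 (SE 0.097) and Ccl3 at 5.19 (SE 0.16). Of 20 homing genes 17 were higher and 2 lower (adjusted p = 8.9e-06, adjusted p = 0.31 with an estimated correlation), among them Ccr2 (4.88, SE 0.11) and the integrin Itgb1 (3.51, SE 0.074). Of 16 co-inhibitory genes 12 were higher and 3 lower (adjusted p = 0.0013, adjusted p = 0.35 with an estimated correlation), such as the checkpoint receptors Lag3 (4.58, SE 0.18), Pdcd1 (3.98, SE 0.13) and Tigit (4.00, SE 0.085). All 30 G2/M genes were higher (adjusted p = 2.8e-09, adjusted p = 0.56 with an estimated correlation), as were 26 of 30 S phase genes (adjusted p = 2.6e-05, 0.56 as the adjusted p with an estimated correlation), with Mki67 at 2.80 (SE 0.15) and Ccnb2 at 2.91 (SE 0.11). Oxidative phosphorylation (39 of 46 higher, 3 lower, adjusted p = 5.0e-06) and interferon response (30 of 51 higher, 13 lower, adjusted p = 0.013) passed too, and each had an adjusted p = 0.56 with an estimated correlation.

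In the other direction 20 of 24 naive and central memory genes were lower in Marilyn T cells and 4 were higher (median -1.28, adjusted p = 6.4e-05, and adjusted p = 0.43 with an estimated correlation). Dapl1 differed by -4.22 (SE 0.078) and the lymph node homing receptor Ccr7 by -3.49 (SE 0.077). Of 21 stress and immediate early genes 18 were lower and 2 higher (adjusted p = 8.9e-06, adjusted p = 0.35 with an estimated correlation), with Junb at -2.79 (SE 0.058). The receptor signalling list did not pass (6 of 24 higher, 15 lower, adjusted p = 0.064), though Nr4a1 differed by -3.82 (SE 0.065). The largest falls were in Atp1b1, a subunit of the sodium pump (-7.40, SE 0.12), Plaur (-7.04, SE 0.17), Pdlim4 (-6.74, SE 0.13), Trnp1 (-6.52, SE 0.10) and Rprm (-6.42, SE 0.15). Foxp3 differed by -1.84 (SE 0.34) at 0.671 ± 0.27 and 2.41 ± 0.82 CPM. Median and mean had opposite signs in the mitochondrially encoded (-0.06 and 0.05, adjusted p = 0.74), apoptosis and p53 (0.19 and -0.25, 0.73) and myeloid lists (0.38 and -0.19, 0.74), none of which passed. Adjusted over the list alone, 31 interferon genes were higher and 14 lower, and the counts of the other lists that passed were the same.

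The same populations were compared between the 3 mice with Marilyn and the 3 with CBir1 T cells alone, which share no animals with the pairs. Lag3 (ENSMUSG00000030124) had 50.8 ± 14 CPM in Marilyn and 0.637 ± 0.19 CPM in CBir1 T cells (SD, n = 3 and 3; log2 6.29, SE 0.29). Gzmk differed by 5.78 (SE 0.25), Ifitm1 by 5.89 (SE 0.22) and Ly6c2 by 5.55 (SE 0.17). Igfbp4 (-7.05, SE 0.12), Pdlim4 (-7.05, SE 0.13), Rprm (-6.86, SE 0.14) and Atp1b1 (-6.05, SE 0.15) were lower in Marilyn T cells. Of 11290 genes 3419 were higher and 3283 lower.

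Of 33 Th1 genes 30 were higher and 2 lower (median 3.90, adjusted p = 2.0e-13, and adjusted p = 0.15 with an estimated correlation), with Ifng at 4.84 (SE 0.16) and Tbx21 at 4.62 (SE 0.18). Of 51 interferon response genes 46 were higher and 3 lower (median 1.08, adjusted p = 1.9e-11, and adjusted p = 0.26 with an estimated correlation), with Irf7 at 1.49 (SE 0.070) and Rtp4 at 1.76 (SE 0.072). Co-inhibitory genes (11 of 16 higher, 2 lower, adjusted p = 0.00022, adjusted p = 0.15 with an estimated correlation) included Pdcd1 (4.03, SE 0.13) and the ectoenzyme Entpd1 (3.88, SE 0.15). Homing (15 of 20 higher, 1 lower, adjusted p = 5.1e-06) and follicular helper genes (10 of 14 higher, 1 lower, 0.0020) passed, with an adjusted p of 0.20 and 0.26 with an estimated correlation. So did the Th17 (7 of 10 higher, 2 lower, adjusted p = 0.025) and myeloid lists (13 of 17 higher, 2 lower, 0.023), with an adjusted p of 0.28 and 0.48 with an estimated correlation.

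Naive and central memory genes were mostly lower in Marilyn T cells given alone (15 of 24 lower, 6 higher, adjusted p = 0.0020, and adjusted p = 0.15 with an estimated correlation), with Ccr7 at -2.83 (SE 0.13). Of 30 S phase genes 28 were lower (median -0.82, adjusted p = 6.8e-09, and adjusted p = 0.28 with an estimated correlation), including Mcm2 (-1.18, SE 0.092) and Mcm3 (-1.17, SE 0.088). The G2/M list did not pass (8 of 30 higher, 7 lower, adjusted p = 0.94), and Mki67 was at 182 ± 17 and 181 ± 45 CPM (log2 0.01, SE 0.13, adjusted p = 0.97). At 1779 UMIs per cell, however, 13.3 ± 1.2% of Marilyn and 8.71 ± 1.2% of CBir1 T cells had an Mki67 UMI, without overlap between the mice (exact permutation p = 0.10, the smallest possible). Mki67 was called higher without clusters 5 and 8 (0.73) and lower without the dividing cells of cluster 4 (-1.09). Cholesterol genes (16 of 24 lower, 2 higher, adjusted p = 0.00071, adjusted p = 0.28 with an estimated correlation) included Idi1 (-1.76, SE 0.15). Stress and immediate early genes (18 of 21 lower, 2 higher, adjusted p = 0.00071) and mitochondrially encoded genes (11 of 13 lower, 0.0020) each had an adjusted p = 0.47 with an estimated correlation. Fos differed by -3.29 (SE 0.31) and Foxp3 by -3.76 (SE 0.43), or -5.07 without Marilyn alone replicate 2, -3.21 without replicate 3 and -2.83 (SE 0.45) with the beta chain required. Adjusted over the list alone, 14 myeloid genes were higher, 17 cholesterol genes and 2 homing genes were lower, and the counts of the other lists that passed were the same.

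Across the 10771 genes tested in both settings, the log2 differences between Marilyn and CBir1 T cells in the pairs and in the mice with 1 graft had a Pearson r of 0.84 and a Spearman rho of 0.72, across genes, which are not independent replicates. Of these genes 2480 were higher in Marilyn T cells in both settings, where independent lists of these sizes would share 1168, and 2258 were lower in both, where they would share 1104. In opposite directions 465 were called, where independent lists would give 2272.

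The tetramer of CBir1 peptide, read through an antibody tag, had a median of 23.5 ± 4.7 UMIs in CBir1 T cells beside Marilyn T cells and 26.7 ± 3.2 alone (SD, n = 4 and 3 mice). Marilyn T cells, which should not bind it, had 9.25 ± 0.96 and 9.33 ± 0.58. On the log2(UMI + 1) scale CBir1 T cells with and without Marilyn T cells differed by -0.19 (exact permutation p = 0.457, two-sided, adjusted p = 0.610 over 20 tests), and by -0.31 without both-graft replicate 4 and -0.10 without both-graft replicate 1. Marilyn lay below CBir1 T cells by 1.24 in the pairs (log2 difference -1.24, exact sign-flip permutation p = 0.125) and in the mice with 1 graft (-1.42, exact permutation p = 0.10), the smallest p that 4 pairs and 3 against 3 mice allow. The median of all antibody tags was 750 ± 118 UMIs in CBir1 T cells beside Marilyn T cells and 1294 ± 203 alone. As a share of these tags the tetramer was higher beside Marilyn T cells by 1.17 percentage points, the reverse direction (exact permutation p = 0.0571, adjusted p = 0.229 over 4 tests). By this measure Marilyn differed from CBir1 T cells by -1.75 percentage points in the pairs (exact permutation p = 0.125) and by -0.52 in the mice with 1 graft (exact permutation p = 0.40), where Marilyn T cells spanned 0.797 to 2.56% and CBir1 T cells 1.90 to 2.23%.

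The receptor contigs gave each population its transgenic chains. The beta chain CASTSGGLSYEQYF with TRBV13-1 made up 99.9 ± 0.075% of beta chain cells in mice with CBir1 T cells alone, and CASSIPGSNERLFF with TRBV26 made up 99.9 ± 0.082% in mice with Marilyn T cells alone (SD, n = 3 each). The design text names Vbeta14 for the sort of CBir1 T cells, and whether that name stands for TRBV13-1 was left open. An alpha chain was found in only 7.77 ± 1.3% and 6.89 ± 0.65% of CBir1 T cells with and without Marilyn T cells, against 60.5 ± 2.9% and 47.7 ± 8.9% of Marilyn T cells with and without CBir1 T cells. With only cells of exactly 1 beta chain counted, the shares in Marilyn T cells were 60.5 ± 2.9% and 54.1 ± 8.7%. Among CBir1 T cells with an alpha chain, 15.3 ± 2.8% beside Marilyn T cells and 9.07 ± 0.32% alone carried one other than the transgenic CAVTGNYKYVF (exact permutation p = 0.0571, two-sided, the smallest possible, adjusted p = 0.221 over 23 tests), and each of the 4 mice lay above each of the 3. With the transgenic beta chain required the share alone was 7.85 ± 0.96%. In 100 drawn alpha chain cells 7.90 ± 1.9 and 7.90 ± 0.96 distinct alpha chains were found, or 7.90 ± 1.9 and 6.84 ± 0.96 with the chain required (exact permutation p = 0.40). These shares rest on 543 and 463 cells with an alpha chain, of which 82 and 42 carried another one. Among those, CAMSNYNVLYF was in 36 and 4 cells and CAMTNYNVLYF in 7 and 0, so the excess lay in these chains. The contigs gave 0 cells of either set more than 1 alpha chain. Whether a cell with another alpha chain also expressed the transgenic one therefore cannot be told.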

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

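In groups of 4 mice Dixon's test for a single distant value was passed in 8 of 110 groups, where about 1 in 20 would pass by chance, and no mouse was left out for it. In CBir1 T cells beside Marilyn T cells these were Ccr2 (ratio 0.921; 4.60, 4.56, 4.77 and 7.25 CPM without TMM factors), Il7r (0.911; 770, 847, 840 and 846), Rad51b (0.926; 2.73, 2.53, 2.48 and 5.84) and mt-Nd3 (0.893; 41.8, 31.2, 32.3 and 31.1). The share of these cells in clusters 5 and 8 had a ratio of 0.863 (0.112, 0.107, 0.188 and 0.694%). In Marilyn T cells beside CBir1 T cells they were Foxp3 (0.855; 0.276, 0.925, 0.831 and 0.835 CPM), the share of cells with an Ifng UMI (0.924; 15.7, 15.8, 15.3 and 9.50%) and the share with a Foxp3 UMI (0.96; 0.0457, 0.0494, 0.145 and 0.0497%).

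Of 51 named genes with a test of the difference, 36 changed differently in CBir1 than in Marilyn T cells. Of all 11736 genes 3587 did. Most of the named genes were chosen for their changes in these same sums, so their larger share is no result of its own. Foxp3, 1 of the 36, was too low in Marilyn T cells to be tested there. Values below are the log2 effect in CBir1 minus that in Marilyn T cells (4 with and 3 without in each). Higher and lower mean this difference and not a larger change. Ccr7, Ext1, Ndufb10 and Cox4i1 had effects of -0.0013, -0.042, -0.012 and -0.014 in CBir1 T cells. In Marilyn T cells they were at -0.61, -0.71, 0.37 and 0.33. Higher in CBir1 T cells were Trnp1 (7.43), Ston1 (6.25), S100a8 (4.53), S100a9 (4.00), Bbc3 (3.02), Klf9 (3.00), Ly6c2 (2.80), Il7r (2.54), Bcl2l11 (1.91), Irf7 (1.88), Isg20 (1.60), Egr1 (1.57), Tsc22d3 (1.48), Dusp2 (1.44), Irgm1 (1.40), Junb (1.12), Gzma (0.89), Tbx21 (0.84), Ext1 (0.67), Jun (0.63) and Ccr7 (0.62). Lower were Rad51b (-3.45), Cenpf (-3.05), Mki67 (-2.84), Rrm2 (-2.55), Top2a (-2.41), Idi1 (-2.31), Igkc (-2.31), Mcm5 (-2.08), Sqle (-2.03), Foxp3 (-1.94), Cycs (-0.87), Cox5a (-0.80), mt-Nd3 (-0.79), Ndufb10 (-0.38) and Cox4i1 (-0.34).

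A beta chain of neither transgene, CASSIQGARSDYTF with TRBV29 and TRBJ1-2, was found in 42 cells, with 11, 3, 9 and 19 cells in the 4 mice with both grafts. It was found in 0 of 11922 beta chain cells of the other 6 mice, which allows a share of up to 0.0252% by counting error alone, with cells taken as independent. Over mice Fisher's exact test gave p = 0.0048 (two-sided, 4 against 6 mice), a test chosen after the counts were seen. It takes the mice as independent, which a chain shared by all 4 of them leaves in doubt. Of these cells 29 lay in cluster 4 and 30 carried the alpha chain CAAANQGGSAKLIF.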

How the results depend on the processing

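The numbers of genes called stayed within 1.5 times in 4 of the 5 comparisons. In Marilyn T cells with against without CBir1 T cells 1359 genes became 12 with the transgenic beta chain required in both groups, 8 without clusters 5 and 8, and 9 with both changes. The median log2 size of the 1359 genes went from 0.32 (SE 0.080) to 0.23 (0.078) with the chain and 0.17 (0.071) without these clusters, with 100 and 99.6% in the same direction. With single mice left out the number ran from 3 (without Marilyn alone replicate 2) to 1835 (without both-graft replicate 4), and the number of lists called from 3 (without both-graft replicate 3) to 8 (without both-graft replicate 2), against 5. The fewest genes were called without the mice whose shares in clusters 5 and 8 set the groups furthest apart. Effects of RNA-poor cells and of single mice were therefore not separated.

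Fewer lists passed camera when the correlation was estimated from the sums: 1 instead of 10 in CBir1 T cells with against without Marilyn T cells, 0 instead of 5 in Marilyn T cells with against without CBir1 T cells, 0 instead of 9 in the pairs, 0 instead of 12 between single grafts and 1 instead of 11 for the difference of effects. With fry 20, 0 and 17 lists passed in the first 3 of these. Fry asks whether a list changed at all and camera whether it changed more than other genes.

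Among the named genes of CBir1 T cells no call changed with a mouse left out. In Marilyn T cells 46 of 154 results lost their call with a mouse left out, and Tbx21 ran from -0.20 to 0.078. Between single grafts Mki67 (0.01) was -0.010 at 1000 genes or more per cell, -0.052 with equal cells, -1.09 without cluster 4, and -0.15 to 0.21 with mice left out. All 92 results of the pairs with a mouse left out and 297 under other alternatives kept their calls, and without the block for the mouse 7424 genes were called instead of 7641.

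The tetramer in CBir1 T cells with against without Marilyn T cells changed direction from -0.19 (log2 of UMIs) to 1.17 (percent of tag UMIs), since the total of tags was lower in those cells, and ran from -0.31 to -0.096 with mice left out. In Marilyn T cells its difference ran from -0.051 to 0.046 with mice left out. Distinct alpha chains in 100 CBir1 T cells differed by 0.00 with all contigs, by -0.053 with contigs of at least 3 UMIs, by 1.06 with the transgenic beta chain required and by -0.63 to 0.88 with mice left out. The cause was not tested.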

Other observations

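CBir1 T cells beside Marilyn T cells also held more message of known targets of the glucocorticoid receptor, a list drawn up after the result was seen. Of 20 targets 7 were put on the list because they had been seen to rise. The 11 measured of 13 added from knowledge of the pathway all rose, with a median log2 of 1.11 (1.61 over all 18), among them Zbtb16 (3.86), Rgs2 (1.68), Txnip (1.52) and Sgk1 (0.54). In Marilyn T cells 1 of the 10 measured added targets rose and 1 fell (median 0.07).

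Alpha chains other than the transgenic one were shared between mice in CBir1 T cells. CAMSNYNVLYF was found in 36 cells beside Marilyn T cells and 4 cells alone, and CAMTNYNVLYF in 7 and 0 cells. Others ran the other way, such as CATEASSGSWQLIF in 0 and 6 cells and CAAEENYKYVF in 0 and 4. All of these cells carried the transgenic beta chain, and the chains were picked after their counts were seen.

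Splits of the mice were chosen after the result was seen. The beta chain and equal cells were alternatives fixed before, but were read as tests of these explanations only afterwards. Of 35 splits of 7 mice only the real one gave as many as 1359 genes in Marilyn T cells (highest other 829), and in CBir1 T cells only the real one gave 5042 (highest other 1234). For the difference of effects 1 of 100 drawn splits gave 3587 (highest other 2996), and the 8 splits of the pairs (7641 against 0) and 10 of single grafts (6702 against 0) are too few to judge. The 1359 calls became 12 with the beta chain required in both groups. With equal cells 1218 genes were called, among them 1088 of the 1359, which argues against fewer cells per sum as the reason for that loss. With the chain required the median log2 size of the 1359 genes was 0.23 (median SE 0.078) instead of 0.32 (0.080), all in the same direction. RNA-poor cells without a beta chain, counted only in the mice with Marilyn T cells alone, may have added to these changes. In these mice 54.5% of cells without a beta chain lay in clusters 5 and 8, against 13.8% of cells with one. How much of the changes was theirs stays open. Leaving out mice does not decide it, since the fewest genes were called without the mice that set these shares furthest apart. Marilyn alone replicates 1, 2 and 3 held 22.9, 19.5 and 14.6% of their cells there (16, 3 and 1545 genes called without each). Both-graft replicates 1, 2, 3 and 4 held 6.18, 7.96, 6.17 and 10.5% (253, 556, 231 and 1835). Fos and Fosb, which kept their calls throughout, may be a change in the cells or in their handling.

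All tests of the glucocorticoid targets were chosen after the rise was seen. Only for those of dividing and RNA-poor cells was the expected outcome written before the test. The rise was also present without the dividing cells of cluster 4 (median of all targets 1.54, 1.10 for the added ones). It was present without the RNA-poor clusters 5 and 8 as well (1.62 and 1.18). These clusters held too small a part of the UMIs to move such medians far, so these tests could hardly have come out otherwise. They show the rise in the other cells only, and whether those cells were in a more resting state was not tested. Handling that reached both populations of the mice with both grafts alike would leave like effects in both. Yet the median difference of effects was 0.95 for the added targets. It was 1.53 over all targets, which include the 7 listed because they rose in CBir1 T cells. Handling that differed between the populations, such as their separate sort gates, was not tested. The 11 measured targets added after 7 were noticed had a higher median than all of 10000 random lists of matched level (percentile 100). Random lists ignore the correlation between genes, and with that estimated the added list passed narrowly in limma's camera (p = 0.044, unadjusted). This would be consistent with glucocorticoid exposure. A circulating hormone would also reach Marilyn T cells, where 2 of the 17 targets measured rose (Dusp1 and Mt2, each 1.14) and 3 fell, among them Fkbp5 (-0.28) and Bcl2l11 (-0.34). Of these 5 only Dusp1 was called with the beta chain required. If Marilyn T cells raised it, however, it would be present in both of their groups, so that comparison does not decide. Between single grafts, where the cells differ too, 11 of 18 targets were higher and 6 lower in Marilyn T cells (median 0.43, percentile 99.5 of random lists, but p = 0.51 in limma's camera with an estimated correlation). They ran from Irs2 (-4.97) to Mt2 (2.95), with Fkbp5 at 1.49. These values and the overlap with genes of resting cells keep the exposure open, and hormone levels were not measured.

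The tests of S100a8 and S100a9 were chosen after the rise was seen. Only for that of the cells with most S100a8 was the expected outcome written before the test. Free RNA of the pooled capture would reach all cells alike, whereas S100a8 rose by 3.21. RNA free in each spleen, or granulocytes caught by chance, would leave like levels in both populations of a mouse if it met them alike. In the 4 mice with both grafts, however, S100a8 was at 62.4 to 230 CPM in CBir1 and at most 37.2 CPM in Marilyn T cells. The ratio within a mouse ran from 6.18 to 8.21, and from 5.48 to 9.50 for 8 other granulocyte genes summed. These ratios argue against a source that met both populations alike. Yet both populations had their highest S100a8 in both-graft replicate 2 (230 and 37.2 CPM), then in replicates 1, 4 and 3. A source in each spleen that reached the populations in unequal amounts was not tested and stays open. All CPM in this paragraph are without TMM factors. T cells that express S100a8 and S100a9 alone would leave those 8 genes unchanged, but they rose by 2.85. In Marilyn T cells they were at 3.57 ± 2.6 CPM beside CBir1 T cells and 10.1 ± 4.0 alone (SD, n = 4 and 3). The 1% of CBir1 T cells with most S100a8 held 48.5% of its UMIs, which leaves open whether granulocytes came with CBir1 T cells only. The gates left out cells with the CD45.1 marker of recipients and marrow, which would remove their granulocytes and T cells joined to them, and each population had its own gate.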
